A study of Caenorhabditis elegans with 12 samples.

How the data were processed

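The series measured RNA in young adult Caenorhabditis elegans hermaphrodites of the wild type strain N2 and of the mutant hrde-1(tm1200), which lacks the germline nuclear Argonaute protein HRDE-1. Per the labels, animals were grown at 23 C for 3 or 4 generations, and RNA was taken from whole animals, from a nuclear-enriched fraction and from a cytoplasmic-enriched fraction. Per the labels' protocols, the fractions were separated over a sucrose cushion, with the cushion layer used as cytoplasm and the pellet as nuclei. RNA was extracted with TRIzol and ribosomal RNA was removed with DNA oligonucleotides and RNase H, without poly(A) selection. The 12 libraries form 6 groups of genotype and fraction with 2 libraries each, from generations 3 and 4. The labels do not say whether the fractions of a generation came from the same culture, so p-values measure the spread between these libraries, which may be technical.

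The deposited table holds the authors' normalized coverage, a signal that is never negative, in 100257 windows of 1000 bases on chromosomes I to V and X. Per the submitters' processing notes, Bowtie 0.12.7 was used. The genome build, the treatment of reads that map to several places, the strand and the scale of the coverage are not given in the sources used here. Per the file headers, the table also marks windows as GRTS or GRH. The sources used here do not spell these names out; in this field they stand for windows subject to germline nuclear RNAi-dependent transcriptional silencing and heterochromatin. They mark 191 and 215 windows, with 25 in both. How the marks were chosen is not given, so the marked windows may have been chosen with these libraries and are not independent evidence of a direction.

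All 12 libraries were normalized together to sums of 839240 to 983821, and every column has a floor of 0.1. Values are therefore close to shares of a library, and not amounts of RNA in a compartment. Below 40, 81.1% to 90.2% of the values of a library lie within 0.0065 of the floor plus a whole multiple of a step between 1.05 and 4.58, which is taken as the value of 1 read. On this scale the libraries held 191226 to 908166 read equivalents, with 652392 to 805512 in whole RNA, 487409 to 908166 in nuclear RNA, 361862 and 520662 in hrde-1 cytoplasmic RNA, and 191226 and 263401 in N2 cytoplasmic RNA. The values are coverage and not counts, so no count model was used, and counts of reads below are read equivalents, rounded to whole reads. Where the 2 libraries of a group held no reads in a region, folds are lower bounds against 3 reads over the group, and with 1 to 3 reads they carry an exact 95% Poisson interval. Intervals and floors cover counting error only.

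Differences were tested per window with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(coverage + 1), two-sided, with Benjamini-Hochberg adjustment over the windows and a threshold of 0.05. All 12 libraries entered 1 fit of 6 groups with 6 residual degrees of freedom, so that all groups shared 1 estimate of the spread. The pseudocount is the power of 10 at or below the median value above the floor, 5.57; values at the floor were taken as zero for this rule. Windows with a mean below 1 were left out, which kept 43933 windows (43.8%). Log2 differences on this scale understate the change of low windows. The generation comparisons added a generation term per genotype, which left 4 residual degrees of freedom. Windows called in the same direction with a gap of at most 1 window were merged into regions. Groups of windows were compared with the other windows by camera in limma with a preset correlation of 0.01, and with an estimated correlation beside it. Region values are means over the windows of a region, and p-values of regions are adjusted over the regions listed for that comparison. Since regions were chosen by their called windows, calls rest on the windows, and region p-values are given only for comparisons of fractions.

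The comparisons, the tests, the alternatives and the rule for naming regions were fixed before the data were examined, except where the closing section says otherwise. The rule took, for each genotype comparison, the 10 regions higher and the 5 regions lower with the most called windows among those that changed the same way in both generations, with ties ordered by the median log2 difference. For nuclear against cytoplasmic RNA it took the 10 highest and 10 lowest called windows, and the text gives the examples among them that it needs. The marks were not known when the tests were fixed, so the tests of marked windows were added when the table was seen.

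The end of chromosome V in the table, 20920000, lies before annotated genes of the reference genome used for comparison, so the table and that reference are different builds. No annotation was used. Gene lists and classes of exon, intron or intergenic windows were therefore not analysed here, and the level of the hrde-1 gene itself was not analysed here. Positions are those of the deposited table, counted from 1. Mitochondrial RNA was not used here.

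The 2 libraries of each group differed by more than sampling noise, with chi-square values per degree of freedom of 1.21 to 2.08, and were kept as separate samples. The method was tested on simulated libraries of the same depths with 200 changed windows. Of 100 windows changed 16-fold it recovered 45 in whole RNA, 51 in nuclear RNA and 65 in cytoplasmic RNA, and of 100 windows changed 4-fold it recovered 6, 8 and 11. In the same simulations it called 0 unchanged windows in whole RNA and 2 in nuclear RNA. In cytoplasmic RNA, where depth differed between genotypes, it called 21 unchanged windows as higher and 12 as lower, and for nuclear against cytoplasmic RNA in N2 it called 30 as higher and 4 as lower. Alternatives were a pseudocount 10 times larger or smaller, no filter, a minimum mean of 10, median scaling (each library shifted to the same median log2 value over the windows tested), quantile normalization within each fraction, a fit of only the groups compared, a replicate block, a minimum change of 2-fold, other gaps in region merging and each library left out in turn. An alternative that thinned all libraries to 190785 read equivalents in 10 draws, with a minimum mean of 10, was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.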

Results

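Coverage of RNA was compared between N2 and the nuclear Argonaute mutant hrde-1 in whole animals and in nuclear-enriched and cytoplasmic-enriched RNA, to ask which transcripts accumulate without HRDE-1 and in which compartment. Each of the 6 groups had 2 libraries, from generations 3 and 4 at 23 C. The libraries held 191226 to 908166 read equivalents, and the N2 cytoplasmic libraries were the shallowest with 191226 and 263401. The 10 highest windows held 2.78% to 6.02% of the signal of a library, and 40.2% to 73.0% of the windows were at the floor of 0.1. Of 100257 windows of 1000 bases, 43933 passed the filter on low values. The genome build is not given in the sources used here, so regions are named by their position in the deposited table without genes, exons or introns. All SD values below are over n = 2 libraries.

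Windows marked GRTS, targets of germline nuclear RNAi silencing, rose in hrde-1 in every fraction. Their mean coverage was 1.14 ± 0.0644 (SD) in N2 whole RNA and 12.7 ± 0.490 in hrde-1 whole RNA. In nuclear RNA it was 2.59 ± 0.344 in N2 and 30.0 ± 0.886 in hrde-1. In cytoplasmic RNA it was 0.517 ± 0.0937 in N2 and 8.41 ± 1.85 in hrde-1. Above the floor, the ratio of hrde-1 to N2 was 12.14 in whole RNA (11.31 and 13.04 in generations 3 and 4), 12.01 in nuclear RNA (13.59 and 10.71) and 19.95 in cytoplasmic RNA (27.47 and 14.50). Of the 170 GRTS windows tested, 25 rose in whole RNA, 67 in nuclear RNA and 29 in cytoplasmic RNA, and 0 fell in any fraction (limma, adjusted over all windows). The log2 difference was above 0 in 168, 168 and 164 of the 170. The filter used the mean of all 12 libraries, so windows low in N2 could pass through their hrde-1 reads. This favours differences above 0 in these counts. The median log2 difference was 1.94 in whole RNA (interquartile range 1.25 to 2.93), 3.03 in nuclear RNA (2.05 to 3.88) and 1.14 in cytoplasmic RNA (0.27 to 2.30), against medians over all windows of 0.00, -0.11 and 0.25. With windows whose N2 reads rounded to 0 set at their bound, and windows at or under the floor in both genotypes left out, the medians were 2.33 over 149 windows, 3.47 over 169 and 0.73 over 72. With a pseudocount 10 times larger they were 0.52, 1.38 and 0.23, and with one 10 times smaller 3.34, 3.68 and 2.42. N2 reads rounded to 0 in 77 of the 170 windows in whole RNA, 16 in nuclear RNA and 152 in cytoplasmic RNA. In cytoplasmic RNA a window was therefore kept mostly by its hrde-1 reads, so the sign of 0.73 is no evidence of a rise. With the preset correlation all 3 fractions passed camera, and all 3 calls held with an estimated correlation, with adjusted p = 1.49e-05 in whole RNA, 3.25e-06 in nuclear RNA and 0.00524 in cytoplasmic RNA. The marks may have been chosen with these libraries and are not independent evidence of the direction.

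**Figure D1:**
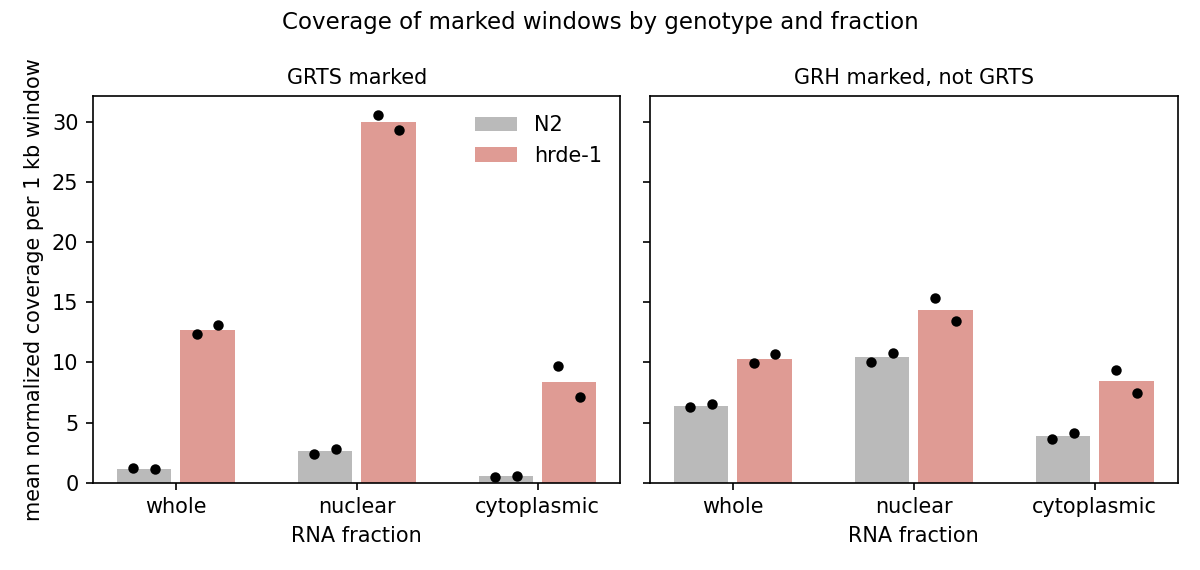
Mean deposited coverage (normalized, no unit) over the windows marked GRTS and those marked GRH but not GRTS, for N2 and hrde-1 in whole, nuclear and cytoplasmic RNA; bars are means of 2 libraries and dots are the libraries. For GRTS windows the hrde-1 means of 12.7, 30.0 and 8.41 stand above the N2 means of 1.14, 2.59 and 0.517, with no overlap of the libraries.

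In whole RNA 43 windows rose and 1 fell in hrde-1, in 22 and 1 regions. The longest was 9 windows on chromosome IV from 913001 to 922000, of which 7 were marked GRTS. Its coverage was 0.311 ± 0.0786 (SD) in N2, from 3 reads over both libraries, and 37.4 ± 4.46 in hrde-1, from 519 reads, a ratio of 174 (95% interval 59.2 to 846). On chromosome V from 17569001 to 17572000, 3 GRTS windows had no N2 reads and a coverage of 53.6 ± 1.05 in hrde-1, at least 82.8-fold higher. On chromosome II from 13245001 to 13248000 coverage was 1.74 ± 1.65 in N2 and 67.3 ± 6.04 in hrde-1. A pair of regions of chromosome V, from 8829001 to 8832000 and from 8871001 to 8874000, both went from 2.10 ± 1.12 to 69.3. Their mean values were the same in every N2 and every cytoplasmic library. These nearly equal values are reported as uncertain, since counting can split reads between like copies. Both regions count among the 43 windows and 22 regions, so these totals may hold the same signal more than once. The other named regions were on chromosome X from 16833001 (0.417 to 27.3), on V from 20298001 (0.217 to 34.4), 18119001 (0.500 to 26.5) and 18440001 (no N2 reads, at least 17.1-fold higher), and on I from 2634001 (no N2 reads, at least 26.8-fold higher). The X region and the region from 18119001 carry no GRTS or GRH mark.

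**Figure D2:**
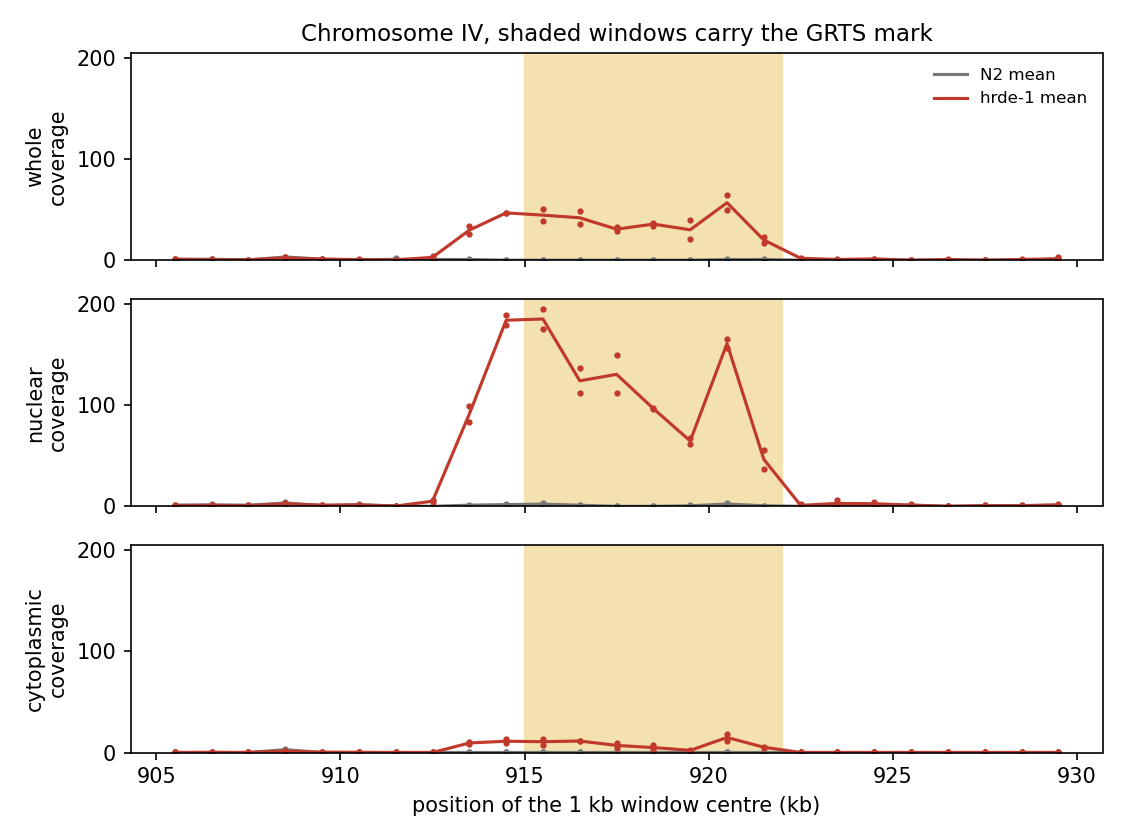
Deposited coverage (normalized, no unit) in 1000-base windows along chromosome IV around the raised region from 913001 to 922000, in each group, with GRTS windows shaded. Mean coverage of the region in hrde-1 was 37.4 in whole RNA, 120.5 in nuclear RNA and 8.61 in cytoplasmic RNA, against 0.311, 1.16 and the floor of 0.1 in N2.

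For whole RNA the lowest adjusted p was 0.000250 (limma), and 1634 windows had an unadjusted p under 0.05. The total of 44 was 8 without the generation 3 hrde-1 whole library and 7 without that of generation 4, 19 and 18 without the N2 whole library of generation 3 or 4, 29 without either hrde-1 nuclear library, and 72 and 70 without the N2 cytoplasmic library of generation 3 or 4. A fit of only the 2 groups compared called 0 windows, thinning to equal depth called 5, a pseudocount 10 times smaller called 22, and no filter called 209 higher and 120 lower. The regions on IV from 913001, on V from 17569001, 8871001 and 20298001, and on I from 2634001 kept a called window without any single library. The region on V from 8829001 lost its call without the generation 3 hrde-1 whole library (limma, adjusted p = 0.0589), and those on II from 13245001 and V from 18440001 lost theirs without either hrde-1 whole library (highest adjusted p 0.0870 and 0.0954). The X region lost its call without either hrde-1 whole library or the generation 4 N2 whole library (highest adjusted p 0.184), and V from 18119001 without any N2 whole, hrde-1 whole or hrde-1 nuclear library (0.459) and with the smaller pseudocount (0.173).

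In nuclear RNA 126 windows rose and 4 fell in hrde-1, in 43 and 4 regions. The region on chromosome IV from 913001 to 922000 went from 1.16 ± 0.173 (SD) in N2 to 120.5 ± 11.07 in hrde-1, from 17 to 1431 reads. The longest run was on chromosome V from 8826001 to 8842000, where 13 windows rose, 10 of them marked GRTS, and coverage went from 1.27 ± 0.289 to 30.3 ± 0.913. On V from 18444001 to 18456000, 12 windows rose, of which 2 were marked GRTS. Coverage there was 0.448 ± 0.0748 in N2 and 22.1 ± 0.0466 in hrde-1 nuclear RNA, 0.129 ± 0.0412 and 3.96 ± 0.428 in whole RNA, and the floor of 0.1 and 0.139 ± 0.0548 in cytoplasmic RNA. On V from 20295001 to 20307000 coverage went from 0.723 ± 0.0931 to 31.7 ± 0.521, on V from 8871001 to 8878000 from 1.84 ± 0.403 to 45.8 ± 1.07, and on III from 13235001 to 13243000 from 0.558 ± 0.0203 to 22.8 ± 2.89. The other 4 named regions were on V from 5189001 (4.14 to 52.7), 5197001 (0.812 to 32.2) and 8880001 (0.680 to 15.8) and on X from 17122001 (0.438 to 14.6).

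**Figure D3:**
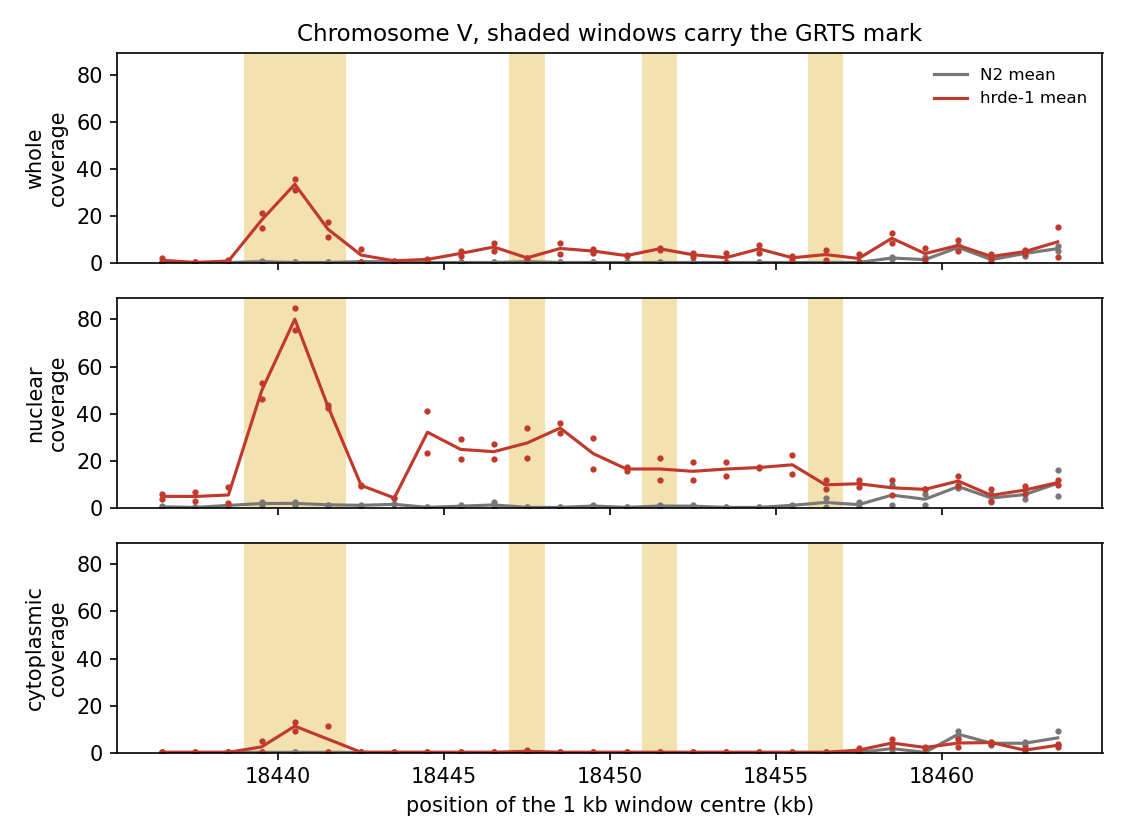
Deposited coverage (normalized, no unit) in 1000-base windows along chromosome V around the region from 18444001 to 18456000, in each group, with GRTS windows shaded. The region reads 22.1 in hrde-1 nuclear RNA against 0.448 in N2 nuclear RNA, and 0.139 in hrde-1 cytoplasmic RNA against the floor of 0.1 in N2.

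For nuclear RNA the lowest adjusted p was 0.000378 (limma), and 1895 windows had an unadjusted p under 0.05. The total of 130 was 19 and 15 without the N2 nuclear library of generation 3 or 4, and 12 and 11 without the hrde-1 nuclear library of generation 3 or 4. A pseudocount 10 times smaller called 12 windows and one 10 times larger 289, a minimum mean of 10 called 42, thinning to equal depth called 5, and no filter called 509 higher and 880 lower. The region on IV from 913001 kept a called window without any single library. Without either hrde-1 nuclear library the regions on V from 8826001 and 8871001 lost their calls (highest adjusted p 0.0533 and 0.0599), as did V from 20295001 without that of generation 4 (0.0513) and V from 18444001 without either N2 nuclear library (0.0622). The regions on III from 13235001, V from 5197001, 5189001 and 8880001 and X from 17122001 lost theirs without any N2 or hrde-1 nuclear library, with highest adjusted p of 0.108, 0.0769, 0.189, 0.232 and 0.182. The smaller pseudocount ended the calls on V from 8826001, 20295001, 5189001 and 8880001 (adjusted p = 0.0538, 0.0577, 0.272 and 0.195), III from 13235001 (0.0538) and X from 17122001 (0.0808). A minimum mean of 10 ended those on V from 5197001 and 5189001 (adjusted p = 0.202 and 0.0615).

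In cytoplasmic RNA 353 windows rose and 28 fell in hrde-1, in 302 and 24 regions, and 278 of the 302 were single windows. On chromosome II from 13245001 to 13250000 and on V from 17569001 to 17574000, N2 had no reads and hrde-1 coverage was 62.4 ± 9.97 (SD) and 49.1 ± 12.7, at least 56.2-fold and 44.6-fold higher. On X from 16833001 to 16837000 and V from 20298001 to 20301000, N2 again had no reads, and coverage was at least 18.8-fold and 23.6-fold higher in hrde-1. The like regions of V from 8828001 and 8870001 both went from 1 to 199 reads, a ratio of 110.1 (95% interval 19.5 to 4370). On IV from 2903001 to 2913000, a stretch with no GRTS or GRH mark, 7 windows rose and reads went from 5 to 144, a ratio of 15.9 (95% interval 6.67 to 49.8), with 3.49 ± 0.194 and 15.6 ± 1.08 coverage in whole RNA. Regions without a mark also rose on X from 1664001 to 1669000 (no N2 reads, at least 9.59-fold higher) and from 4712001 to 4715000 (4.30 ± 5.93 to 49.5 ± 2.88).

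For cytoplasmic RNA the lowest adjusted p was 0.000137 (limma), and 7382 windows had an unadjusted p under 0.05. Median scaling, which gives all libraries the same median, shifted every log2 difference by -0.33 and the median over all windows from 0.25 to -0.08, and called 110 windows higher and 92 lower in place of 353 and 28. Every library moved the total of 381 by over 1.5 times when left out. In the order generation 3, generation 4, it was 1214 and 4426 without the N2 cytoplasmic library, 56 and 54 without the hrde-1 cytoplasmic, 125 and 127 without the N2 whole, 67 and 68 without the hrde-1 whole, 123 and 118 without the N2 nuclear, and 115 or fewer without either hrde-1 nuclear library. A fit of only the 2 groups compared called 0 windows, thinning to equal depth called 18, quantile normalization 164, and pseudocounts 10 times larger and smaller 192 and 986. Of the 10 named regions, 7 kept a called window without any single library. The part of the IV region from 913001 to 918000 lost its call without either hrde-1 cytoplasmic library (highest adjusted p 0.0562) and with the larger pseudocount (0.0632), X from 1664001 lost its call without either hrde-1 cytoplasmic library (0.0753), and X from 4712001 lost its call without that of generation 4 (0.0769).

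Fewer regions fell. The window of chromosome III from 4175001 to 4176000 fell from 239.6 ± 18.7 (SD) to 73.2 ± 8.88 in whole RNA and from 225.4 ± 11.7 to 81.4 ± 10.4 in nuclear RNA (limma, adjusted p = 0.00847 and 0.0175). In cytoplasmic RNA it read 170.0 ± 13.5 and 86.6 ± 31.1. On chromosome II from 8784001 to 8790000, 5 windows fell in cytoplasmic RNA, from 79.3 ± 18.6 to 14.5 ± 3.49, with a lowest adjusted p of 0.000352. This region read 73.0 ± 2.92 and 29.3 ± 1.29 in whole RNA and 72.9 ± 9.42 and 28.2 ± 1.21 in nuclear RNA, and its window from 8788001 fell in nuclear RNA from 211.0 ± 32.0 to 88.4 ± 10.4 (adjusted p = 0.0302). The cytoplasmic call on II held with any single library left out. The III window lost its whole RNA call without any of the 4 whole libraries (highest adjusted p 0.368) and its nuclear call without any N2 whole, N2 nuclear or hrde-1 nuclear library (0.281). The nuclear call from 8788001 was lost without any of the 8 whole and nuclear libraries (0.545). A pseudocount 10 times smaller ended the nuclear calls from 4175001 and 8788001 (adjusted p = 0.0940 and 0.114), and no filter ended the whole RNA call from 4175001 (0.0635). A fit of only the groups compared ended that whole RNA call and the cytoplasmic call on II (0.397 and 0.107).

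The other lower windows named by the rule held few reads. In nuclear RNA, IV from 16419001 held 13 reads in N2 and under 1 in hrde-1, and III from 1919001 held 12 and 0 (limma, adjusted p = 0.0387 and 0.0359). In cytoplasmic RNA, I from 6011001 and I from 14657001 held 6 reads in N2 and 0 in hrde-1, and I from 2185001 and II from 5953001 held 4 and 0, with adjusted p of 0.0272 to 0.0438. The calls from 16419001 and 1919001 ended with median scaling (adjusted p = 0.0607 and 0.0502), a pseudocount 10 times smaller (0.193 and 0.225) and a fit of only the groups compared (0.278 and 0.307), and that from 16419001 with quantile normalization (0.0961). A pseudocount 10 times larger ended the 4 cytoplasmic calls, with adjusted p of 0.0635 from 6011001, 0.119 from 14657001, 0.151 from 2185001 and 0.147 from 5953001, as did a fit of only the groups compared (0.302 for each). Quantile normalization ended those from 2185001 and 5953001 (0.0579 and 0.0585), and no filter that from 14657001 (0.0722). The call from 16419001 was lost without any library but the generation 3 hrde-1 whole library (highest adjusted p 0.268). The call from 1919001 was lost without any cytoplasmic or hrde-1 library (0.267), and without either N2 nuclear library the window was below the filter. From 6011001 the call held only without the N2 cytoplasmic libraries or the generation 4 N2 whole library, and from 14657001 only without the N2 cytoplasmic libraries or the generation 3 N2 nuclear library (highest adjusted p 0.114 and 0.130). From 2185001 and 5953001 it held only without the generation 4 N2 cytoplasmic library (0.159 and 0.151).

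Windows marked GRH, a mark of nuclear RNAi-dependent heterochromatin, had smaller median differences than GRTS windows. The groups share 22 windows and were not tested against each other. Mean coverage was 5.87 ± 0.115 (SD) in N2 and 11.2 ± 0.707 in hrde-1 whole RNA, 9.62 ± 0.700 and 16.52 ± 1.65 in nuclear RNA, and 3.47 ± 0.384 and 9.202 ± 1.48 in cytoplasmic RNA. Of the 187 GRH windows tested, 4 rose in whole RNA, 10 in nuclear RNA and 12 in cytoplasmic RNA, and 0 fell. The median log2 differences were 0.71, 0.35 and 0.81, and with bounds as above 0.84 over 171 windows, 0.37 over 186 and 0.56 over 97. As a group they passed camera in each fraction, and the calls held with an estimated correlation, with adjusted p = 0.000503, 0.00114 and 0.0168. Among the 165 GRH windows not marked GRTS, 2, 2 and 6 rose. Their mean coverage was 6.41 ± 0.169 in N2 and 10.3 ± 0.560 in hrde-1 whole RNA, and 10.4 ± 0.554 and 14.4 ± 1.38 in nuclear RNA. In cytoplasmic RNA it was 3.87 ± 0.401 and 8.42 ± 1.38. Median log2 differences of this set were 0.55, 0.24 and 0.72 (camera, estimated correlation, adjusted p = 0.000825, 0.00369 and 0.0243). The GRH marks, too, may have been chosen with these libraries.

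The windows that rose overlapped between fractions. Whole and nuclear RNA shared 41, with 0.123 expected for independent lists, whole and cytoplasmic RNA shared 37 (0.346 expected), and nuclear and cytoplasmic RNA shared 40 (1.01 expected). The fractions used different libraries but shared 1 estimate of the spread per window, so part of an excess may come from that. In all, 36 windows rose in all 3 fractions. Windows with no mark were 16 of the 43 that rose in whole RNA, 57 of the 126 in nuclear RNA and 318 of the 353 in cytoplasmic RNA, where median scaling called 110 higher in place of 353 and the total of 381 was 54 to 4426 with 1 library left out.

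Nuclear and cytoplasmic RNA differed at many windows within each genotype. Since the libraries were scaled to like sums, higher in nuclear RNA means a larger share of the nuclear library. It does not mean that most of a transcript was in the nucleus. In N2, 6163 windows were higher in nuclear and 873 in cytoplasmic RNA, and in hrde-1 2034 and 1012, with 1146 nuclear-higher windows shared (285 expected for independent lists) and 641 cytoplasmic-higher windows shared (20.1 expected). The excess of nuclear calls depended on coverage. At a mean coverage of 1 to 3, nuclear and cytoplasmic calls were 2152 and 19 in N2 and 799 and 14 in hrde-1. Over 100 they were 252 and 218 in N2 and 208 and 182 in hrde-1. Between these levels the N2 median log2 difference went from 1.30 to 0.08. In N2 the window of chromosome III from 7278001 read 546.8 ± 43.01 (SD) in cytoplasmic and 8.31 ± 3.27 in nuclear RNA, and in hrde-1 363.2 ± 138 and 10.64 ± 6.73. That of I from 8781001 read 388.6 ± 202 and 5.46 ± 2.58 in N2, and 169.2 ± 54.02 and 1.54 ± 0.686 in hrde-1, where the nuclear value rests on 2 reads (ratio 107.6, 95% interval 29.3 to 896). Nuclear RNA was higher on I from 7867001, at least 10.6-fold in N2, where cytoplasmic RNA had no reads, and with 64 reads against 1 in hrde-1 (ratio 47.6, 95% interval 8.24 to 1909). On III from 8863001 it was at least 10.5-fold higher in N2 and read 66.4 ± 5.41 against 4.48 ± 4.33 in hrde-1. The window of I from 4462001, marked GRTS and GRH, read 64.4 ± 4.42 in hrde-1 nuclear and 4.43 ± 2.79 in N2 nuclear RNA with no cytoplasmic reads in either genotype, at least 20.6-fold higher in hrde-1 and with no bound above 1 from the 8 nuclear reads of N2. On the X chromosome, 9.87% of the windows tested were higher in nuclear RNA in N2 and 2.94% in hrde-1, and 4.85% and 4.18% were higher in cytoplasmic RNA. On the autosomes the nuclear shares were 13.7% to 16.3% in N2 and 3.93% to 5.71% in hrde-1. Their cytoplasmic shares were 1.16% to 2.03% and 1.72% to 2.33%. The lower nuclear share in hrde-1 was thus not particular to X.

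For nuclear against cytoplasmic RNA the lowest adjusted p was 1.37e-08 in N2 and 7.34e-08 in hrde-1 (limma). Median scaling shifted every log2 difference by -0.76 in N2 and -0.39 in hrde-1, and the medians over all windows from 0.82 and 0.30 to 0.06 and -0.09. It called 661 windows higher in nuclear and 1782 in cytoplasmic RNA in N2, and 830 and 1650 in hrde-1. A fit of only the groups compared called 0 windows in hrde-1 and 7648 in N2. A minimum mean of 10 gave 723 windows higher in nuclear and 1060 in cytoplasmic RNA in hrde-1, and 1998 and 793 in N2. Thinning to equal depth gave 520 and 561 in N2 and 328 and 465 in hrde-1 (medians over 10 draws). The N2 total of 7036 was 1501 and 1275 without the nuclear N2 library of generation 3 or 4. The hrde-1 total of 3046 was 947 and 1659 without the nuclear hrde-1 library of generation 3 or 4, 1582 and 1049 without the cytoplasmic one, and 4577 without the generation 3 N2 cytoplasmic library. Without the generation 3 nuclear or the generation 4 cytoplasmic hrde-1 library, fewer windows were higher in nuclear than in cytoplasmic RNA in hrde-1 (441 and 506, and 512 and 537).

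The transcripts raised in hrde-1 whole RNA were not all distributed alike between nucleus and cytoplasm. Over the 43 raised windows the median log2 difference of nuclear to cytoplasmic RNA in hrde-1 was 0.80 (interquartile range -0.07 to 3.16), with 15 windows higher in nuclear RNA and 0 lower. Of the 22 raised regions, 8 were higher in nuclear RNA in hrde-1 and 0 were higher in cytoplasmic RNA. The IV region from 913001 had a log2 difference of 3.66 ± 0.54 (SE; limma, adjusted p = 0.000182). By contrast, V from 17569001 had -0.71 ± 0.50 (adjusted p = 0.308) and II from 13245001 had -0.71 ± 0.52 (0.308). Against the IV region, 14 of the other 21 regions had a lower ratio of nuclear to cytoplasmic RNA (limma, adjusted over the regions). As a set the 43 windows lay above the other windows in camera with the preset correlation (p = 1.83e-05), and the call held with an estimated one (p = 0.0139). The set median was 0.46 without the generation 3 N2 whole library (camera p 0.0758), 0.78 without the generation 3 hrde-1 whole library (camera p 0.0773) and 0.76 without that of generation 4 (camera p 0.687). With no filter, 209 windows had risen and their median was 0 (camera p 0.0173). It was 0.37 with median scaling and 0.44 with a minimum mean of 10. At equal depth it was below 0 in each of the 7 draws of 10 that gave a value, -0.82 to -0.25 over 2 to 9 windows (camera p 0.400 to 0.944).

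**Figure D4:**
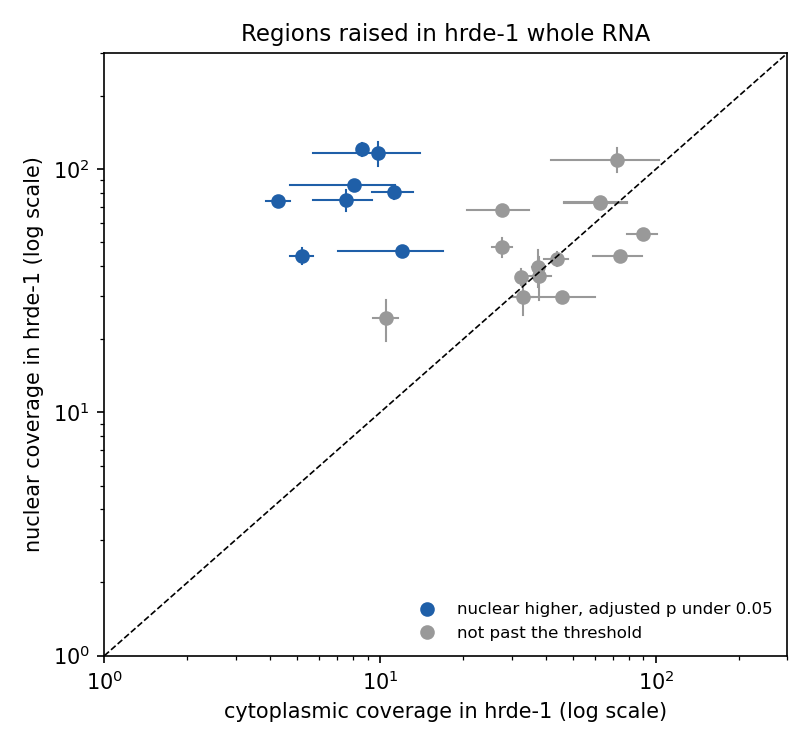
Mean coverage in hrde-1 cytoplasmic RNA (x axis) and hrde-1 nuclear RNA (y axis), both normalized without a unit and on log axes, of the 22 regions raised in hrde-1 whole RNA; points are means of 2 libraries, lines span the libraries, and blue marks the 8 regions higher in nuclear RNA. The IV region from 913001 reads 8.61 in cytoplasmic and 120.5 in nuclear RNA, and V from 17569001 reads 74.2 and 44.1.

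As shares of a library, GRTS windows were higher in nuclear than in cytoplasmic RNA in hrde-1, with a median log2 difference of 2.77. Of the 170 windows, 95 were higher (55.9%) and 1 was lower, against 4.43% higher among windows without the mark. The median was 1.05 with a pseudocount 10 times larger and 3.64 with one 10 times smaller. In N2 the median was 1.01 and 21 were higher. Medians with bounds set fractions whose reads rounded to 0 at their bound and left out windows at or under the floor in both fractions. They were 2.27 over 167 windows in hrde-1 and -0.33 over 69 in N2. In N2, cytoplasmic reads rounded to 0 in 152 of the 170 windows, so -0.33 is mostly a median of lower bounds. It does not oppose the fitted N2 median of 1.01. With an estimated correlation the hrde-1 call held in camera (adjusted p = 0.000653) and N2 had adjusted p = 0.324. Between the genotypes, 0 single windows passed the test of the difference (limma, lowest adjusted p 0.181, 5061 windows at an unadjusted p under 0.05). The GRTS median of that difference was 1.496 on the log2(coverage + 1) scale (camera, adjusted p = 1.26e-33 preset and 0.000515 estimated), against -0.42 for all windows. Summed reads gave the opposite order. The ratio of nuclear to cytoplasmic reads over the GRTS windows was 3.52 in hrde-1 and 5.84 in N2, a ratio of ratios of 0.603 (95% interval 0.423 to 0.837, counting error only, exact p = 0.00170). Windows without a mark had ratios of 0.989 and 1.10. The N2 cytoplasmic libraries held 39 reads in the GRTS windows, and no direction of the genotype difference is stated. Without the N2 cytoplasmic library of generation 3 or 4 the test called 10 windows higher and 318 lower, or 169 and 2075. It called 59 higher and 8 lower with a pseudocount 10 times larger, and 454 and 911 with no filter.

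GRH windows were higher in nuclear RNA in both genotypes, with a median of 1.71 in N2 and 1.34 in hrde-1 (0.58 over 163 windows and 1.08 over 178 with bounds), 60 and 42 windows higher and 0 and 1 lower. Both calls held with an estimated correlation (camera, adjusted p = 0.0255 and 0.00621).

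Between generations 4 and 3, N2 had 5 windows that differed and hrde-1 had 0 (limma, lowest adjusted p 0.967 in hrde-1, with 2207 windows at an unadjusted p under 0.05). The fractions of a genotype and generation may come from 1 culture. The p-values here therefore do not separate generation from culture or library preparation. In N2 the windows of chromosome II from 11012001 and 11013001, IV from 12109001 and V from 4653001 were lower in generation 4, with log2 differences of -2.97, -3.24, -2.79 and -2.86 (adjusted p = 0.00195), and V from 10021001 was higher (1.25, adjusted p = 0.00588). In hrde-1 their values were -1.69, -1.45, -1.30, -1.54 and 0.12. At the 4 lower windows the generation 4 library read below the generation 3 library in all 6 groups. The difference between genotypes passed at 0 windows (limma, lowest adjusted p 0.887, 2253 windows at an unadjusted p under 0.05), so the genotypes were not shown to differ. The N2 total of 5 was 0 with a pseudocount 10 times smaller and 0 with no filter, 19 with a pseudocount 10 times larger, 20 with quantile normalization, 9 with median scaling, 11.5 at equal depth (median of 10 draws), 3 without the generation 3 N2 whole library and 1 without the generation 3 N2 nuclear library. In hrde-1 it was 2 without either N2 cytoplasmic library and 1 with a pseudocount 10 times larger. GRTS windows and windows raised in whole RNA had median generation differences of -0.21 to 0.05, and the lowest camera p was 0.0882.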

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

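All tests of technical explanations in this part were chosen after the results were seen. The results below stand apart because the difference between nuclear and cytoplasmic RNA was not the same in hrde-1 and N2, by a test of that difference over the regions listed for each comparison (limma, Benjamini-Hochberg). The regions had been chosen for a difference in 1 fraction, which by itself favours such a result, and over all 43933 windows 0 single windows passed (lowest adjusted p 0.181). In all there were 17 results, with 13 distinct regions once overlapping ones are counted together.

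Positive values mean a larger nuclear excess in hrde-1. Among regions raised in hrde-1 the log2 difference was 2.69 on chromosome IV from 913001 to 922000 (adjusted p = 0.0353 among the whole RNA regions, 0.00802 among the nuclear ones) and 2.63 in its part to 918000 (0.0309). It was 3.95 on V from 18444001 (adjusted p = 0.00269), 2.53 on V from 5197001 (0.0309), 3.13 on X from 17122001 (0.00802) and 2.87 on V from 8880001 (0.00802). On V from 15579001, a window raised in whole RNA that was named only after its values were seen, it was -3.22 (adjusted p = 0.0352). That window read 13.3 ± 3.82 (SD, n = 2) in N2 and 29.9 ± 1.20 in hrde-1 nuclear RNA, and 1.68 ± 2.23 and 45.6 ± 20.3 in cytoplasmic RNA.

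Among regions lower in hrde-1 it was -2.85 on IV from 16419001 and -2.81 on III from 1919001 (adjusted p = 0.00391 for both). It was 0.91 on II from 8788001 (adjusted p = 0.0165) and 1.04 on II from 8784001 (0.0223). The 4 windows with 4 or 6 N2 cytoplasmic reads had 3.50 on I from 6011001 (adjusted p = 0.00753), 3.09 on I from 14657001 (0.00833), 2.96 on I from 2185001 (0.00833) and 2.56 on II from 5953001 (0.0142).

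GRTS windows as a group had a median difference of 1.496 (camera, adjusted p = 1.26e-33 with the preset and 0.000515 with the estimated correlation). A technical explanation is that adding 1 to values near the floor shrinks the N2 difference. The read ratio of 0.603 is below 1 where the median is above 0, which this explanation allows. It does not decide, since a sum weighs windows by their reads and a median does not. The like regions on V from 8829001 and 8871001 each held 186 of the 1391 hrde-1 cytoplasmic reads of the GRTS windows. At the 5 raised regions with positive values the reads decide nothing, since 0 had an interval of the ratio of ratios above 1 and N2 cytoplasmic RNA held 0 or 1 reads in each. At V from 15579001 the reads gave a ratio of ratios of 0.0901 (95% interval 0.00216 to 0.618, counting error only, exact p = 0.00453), which rests on 1 N2 cytoplasmic read. A difference between genotypes in export or stability of these RNAs was not tested and stays open.

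The raised regions differed in their ratio of nuclear to cytoplasmic RNA within hrde-1, where 14 of 21 regions had a lower ratio than the IV region from 913001 (limma, adjusted over the regions). For the IV region and V from 17569001 the log2 ratios differed by 4.42 at equal depth (4.29 to 4.77 over 10 draws). This says nothing about unequal depth, since both regions were read in the same libraries and thinning kept their expected values. The other regions were not compared at equal depth. Reads that map to several places were not tested here. No biological explanation was tested, because the groups do not separate export from stability.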

How the results depend on the processing

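Thinning to equal depth with a minimum mean of 10 was chosen after seeing the data, as were all alternatives for GRTS medians; the other alternatives were fixed before. Gene-list alternatives were not run, because no annotation of the build was used. The GRTS medians of hrde-1 against N2 in the 3 fractions kept their direction in the alternatives run for them. So did that of nuclear against cytoplasmic RNA in hrde-1. Their camera p-values also stayed under the threshold, but these used only the preset correlation, with which the highest reported p was 4.30e-16. The estimated correlation, with an adjusted p of 0.00524 in cytoplasmic RNA, was not run under the alternatives. Whether the calls with it would hold there was therefore not tested. The GRTS medians of nuclear against cytoplasmic RNA in N2 and of the genotype difference were not run under these alternatives. The N2 median was 1.01, and -0.33 with bounds, where it is mostly a median of lower bounds. The median of the raised set (0.80) turned to -0.37 at equal depth, over the 7 of 10 draws that gave a value, with a median camera p of 0.586 and 2 to 9 windows in the set. With no filter it was 0 (camera p 0.0173). The balance of higher and lower windows also turned. In nuclear RNA it went from 126 higher and 4 lower to 509 and 880 with no filter. For nuclear against cytoplasmic RNA in N2 it went from 6163 and 873 to 520 and 561 at equal depth. In hrde-1 it went from 2034 and 1012 to 723 and 1060 with a minimum mean of 10, 328 and 465 at equal depth, 441 and 506 without the generation 3 nuclear hrde-1 library and 512 and 537 without the generation 4 cytoplasmic hrde-1 library. Median scaling, which shifted every log2 difference by -0.76 in N2 and -0.39 in hrde-1 and so by construction moved this balance toward cytoplasmic RNA, gave 661 and 1782 in N2 and 830 and 1650 in hrde-1. Gaps of 0 or 3 windows in merging, run for the region counts of the 3 genotype comparisons, and a 2-fold minimum, run for their window counts, left these within 1.5 times. The cause of each change below was not tested, except where fewer windows or libraries entered by construction.

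A pseudocount 10 times larger gave 289 windows in nuclear RNA (130 as reported), 192 in cytoplasmic RNA (381), 67 for the genotype difference of nuclear against cytoplasmic RNA (0), 19 for N2 generations (5) and 1 for hrde-1 generations (0). One 10 times smaller gave 22 in whole RNA (44), 12 in nuclear RNA, 986 in cytoplasmic RNA and 0 for N2 generations. No filter gave 329 in whole RNA (209 higher, 120 lower), 1389 in nuclear RNA (509 and 880), 1365 for the genotype difference and 0 for N2 generations. A minimum mean of 10, which tests fewer windows, gave 42 in nuclear RNA, and 2791 and 1783 for nuclear against cytoplasmic RNA in N2 (7036) and hrde-1 (3046).

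Median scaling gave 202 in cytoplasmic RNA, 2443 for nuclear against cytoplasmic RNA in N2 and 9 for N2 generations. Quantile normalization gave 164 in cytoplasmic RNA and 20 for N2 generations. A fit of only the groups compared, with fewer libraries, gave 0 in whole RNA, 0 in cytoplasmic RNA and 0 for nuclear against cytoplasmic RNA in hrde-1, and no value for the raised set. Thinning, which loses reads and windows, gave 5, 5 and 18 in whole, nuclear and cytoplasmic RNA, 1082 and 799 for nuclear against cytoplasmic RNA in N2 and hrde-1 and 11.5 for N2 generations.

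Leaving out 1 library gave 7 to 72 in whole RNA, 11 to 142 in nuclear RNA, 54 to 4426 in cytoplasmic RNA, 1275 to 7943 and 947 to 4577 for nuclear against cytoplasmic RNA in N2 and hrde-1, 0 to 2244 for the genotype difference, 1 to 7 for N2 generations and 0 to 2 for hrde-1 generations. The median of the raised set was 0.46 to 0.95 and lost its call without the generation 3 N2 whole library or either hrde-1 whole library. A group left with 1 library was assumed to vary like the others.

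Generation numbers were not taken to pair the libraries, since only 5 of 15 correlations between groups were over 0.1. All 15 were above 0 (0.0383 to 0.179, over 16771 windows), so libraries of a generation shared a small part, which the reported fit leaves out. With generation as a replicate block the counts were 43 in whole and 435 in cytoplasmic RNA, within 1.5 times the reported count in nuclear RNA, 7390 and 3172 for nuclear against cytoplasmic RNA in N2 and hrde-1, and the median of the raised set was 0.74. Of the named region calls, a fit of only the groups compared ended 28, a pseudocount 10 times smaller 11 and 10 times larger 5, quantile normalization 3, and median scaling, no filter, a minimum mean of 10 and the block 2 each, all without a change of direction. The calls the block ended were those in nuclear RNA on IV from 16419001 and III from 1919001 (adjusted p = 0.0628 and 0.0508). In simulated libraries at the deposited depths, where N2 cytoplasmic RNA was the shallowest, the cytoplasmic comparison called 21 unchanged windows higher and 12 lower. At equal depth with a minimum mean of 10 it called 2 and 2. That run fitted 16793 windows in place of 44020, so the drop cannot be credited to depth alone.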

Other observations

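The test of depth for cytoplasmic RNA and the tests of other splits by generation were fixed before their results were seen; all other tests in this part were chosen afterwards. Of the 191 windows marked GRTS, 84 were on chromosome V and 0 on X, while unmarked regions of X rose in hrde-1 in all 3 fractions from 16833001, in nuclear RNA from 17122001 and in cytoplasmic RNA from 1664001 and 4712001. Of the windows highest in cytoplasmic RNA, II from 13834001 had log2 nuclear against cytoplasmic differences of -4.79 in N2 and -4.44 in hrde-1, and II from 14804001 had -4.97 and -4.30 (limma, highest adjusted p 7.34e-08). On X, the windows from 12843001 and 11935001 were higher in cytoplasmic RNA by a read ratio of 51.2 (95% interval 18.998 to 194) and 62.1 (16.02 to 532) in N2, from 4 and 2 nuclear reads, and of 24.2 (9.05 to 91.2) and 38.3 (10.1 to 324) in hrde-1, again from 4 and 2. On V from 15585001, coverage in nuclear RNA was 31.4 and 32.7 in the N2 libraries and 2.03 and 2.65 in the hrde-1 libraries, a log2 difference of -3.31 that did not pass (limma, adjusted p = 0.132).

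More windows rose in cytoplasmic than in whole RNA, 353 against 43. The count depends on scaling too. Median scaling shifted every log2 difference by -0.33 in cytoplasmic and -0.005 in whole RNA, and called fewer windows higher in cytoplasmic RNA. Depth was unequal between the N2 and hrde-1 cytoplasmic libraries, and at equal depth the number in cytoplasmic RNA was 3.21 times that in whole RNA (median of 10 draws, lowest 1.33, over 1.5 in 9 of 10). In 1 draw it was 16 against 0, which gives no ratio and was taken as the highest. The draws held 12 to 20 windows in cytoplasmic and 0 to 9 in whole RNA, so few calls that depth cannot be told apart from the other explanations. Nuclear RNA carried into the hrde-1 cytoplasm cannot be told apart either by the test run. The 316 windows called in cytoplasmic and not in whole RNA had a median nuclear minus whole difference in N2 of 0.0963. Random windows of the same level had 0.0999 (0.0204 to 0.189). Carry-over of all nuclear RNA alike is limited by V from 18444001, with 344 nuclear and 0 cytoplasmic reads in hrde-1. IV from 913001 held 1431 and 74. The 316 windows were not examined this way. A rise of these transcripts without HRDE-1 is a hypothesis, and their whole RNA difference of 0.107, against -0.0282 (-0.0841 to 0.0270) in random windows, is in line with it. That rise is small beside the calls in cytoplasmic RNA.

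Regions raised in nuclear RNA may lie toward chromosome ends. The 38 regions on autosomes had a mean relative distance from the chromosome centre of 0.593, against 0.517 (0.422 to 0.610) in 10000 random sets of the same chromosome and N2 level (one-sided permutation p = 0.0546), so the data do not decide. A like pair of regions of chromosome V, 42 kb apart, from 8829001 and 8871001, may share reads between near-identical copies: 56.7% of 30 values differed by at most 1 read, with a mean difference of 0.313 times counting noise.

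Other splits of the libraries bear on the generation results. Of the 10 splits of the 6 N2 libraries, 3 gave as many windows as the real 5, and the highest other gave 3212; 10 splits cannot give a share under 0.05. The model keeps the fractions apart, so the 2 splits with that highest count compare only the N2 cytoplasmic libraries, 1 against 1. The spread between these libraries then does not enter the estimate, and 1 read is worth 4.58 and 3.15 in them. That count therefore does not show a difference beyond counting error. Of the 4 splits with 1 library of each fraction on each side, the real one gave 5 windows and the other 3 gave 0. In hrde-1 all 10 splits gave 0, again too few for a share under 0.05. For the difference between genotypes, the real count was 0, which all 100 of 100 splits reach whatever they hold, so the splits (highest 2122) say nothing about chance.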
